A study of Branchiostoma lanceolatum and Danio rerio with 24 samples.

How the data were processed

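Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in whole embryos of zebrafish (Danio rerio) and of the amphioxus Branchiostoma lanceolatum, an invertebrate chordate. Zebrafish embryos were grown at 28 °C to 80% epiboly, a stage of gastrulation, and amphioxus embryos at 19 °C to 15 h, per the labels' protocols. Each species has a control group and groups in which the FGF, Nodal, RA (the usual abbreviation of retinoic acid) or Wnt pathway was modified. The labels do not say which compounds were used, or whether a pathway was raised or lowered. The 24 samples comprise 10 of zebrafish, 2 in each group, and 14 of amphioxus, with 4 control, 4 FGF, 2 Nodal, 2 RA and 2 Wnt samples.

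The processed data are 10 peak lists, 1 per group, and none per sample. Reads were aligned with Bowtie2 and handled with SAMtools, per the submitters' processing notes, which give no versions and name GRCz10 (danRer10) as a genome build. That build is read here as the zebrafish one from its name. The amphioxus assembly, the peak caller, the handling of transposase offsets and duplicates, and the way 4 samples were combined into 1 list are not given in the sources used here. The labels call the lists IDR peaks, after the irreproducible discovery rate, a measure of how well peaks recur between replicates. The deposited files have no header, and their columns follow the layout of an IDR peak record. The deposited score runs up to 1000 and follows from the global IDR, and between 44.0% and 60.1% of the peaks of a list lie at that cap. The lowest −log10 of the global IDR in every deposited list is 1.0, so the authors kept peaks with an IDR of up to 0.1. The deposited fold enrichment is a ratio of signal to background, as peak callers write it. The deposited −log10 p-value belongs to the single peak, and the column read as its −log10 q-value was not used. These peak values are the authors' own and serve below only to rank or describe peaks within 1 list.

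Peaks within a list did not overlap each other. Control peaks with no overlap of at least 1 bp in a treatment list were counted as absent from it, and treatment peaks with no overlap in the control list as new. The score had been planned as the rank of a peak; because it is capped, the −log10 p-value was taken instead, a choice made after the files were seen. Error was estimated by resampling genome blocks of 1 Mb, or whole scaffolds where shorter, 1000 times (95% intervals). These intervals cover the spread along the genome and not the spread between samples, since each group is 1 list. No p-value below tests a treatment against replicate error: each compares lists. Read depth per sample is unknown, so differences in list length can come from depth as well as from accessibility, and an absent peak is not a measured fall in accessibility.

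Joint absence from a pair of treatment lists was measured by a Mantel-Haenszel odds ratio over 30 strata, the 10 deciles of control rank by 3 groups of peak width. Expected counts assume independent absence within strata. The mean number of lists lacking a peak, planned for the species comparison, equals its expectation by construction, so the control peaks absent from all 4 lists were used. Sharing of new peaks was set against 100 circular shifts of one list along the concatenated sequences, with an empty gap of 100 kb after each sequence. Shifted peaks can fall in these gaps, which lowers the overlap they give. Windows of 100 kb in zebrafish and 50 kb in amphioxus with at least 5 peaks were tested by a two-sided exact binomial test against the genome-wide share, and chromosomes or scaffolds with at least 100 control peaks by Fisher's exact test, two-sided. Benjamini-Hochberg adjustment was made over the windows of 1 list and direction, and over 200 chromosome tests in zebrafish and 608 scaffold tests in amphioxus, with a threshold of 0.05. Alternatives required an overlap of 50% of each peak, took the stronger 50% of a list, shortened the lists of a species to equal length, left out the strata or doubled the window size. Species were compared by resampling both genomes, adjusted over 6 pairs. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.

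The functions were tested on simulated data first. With the real zebrafish control peaks and FGF and RA absence rates (210860 peaks), simulated odds ratios of 1.0, 2.0 and 4.0 were estimated at 1.0, 1.99 and 4.02. Of 200 windows made fully absent, 69.5% were called for zebrafish FGF (13000 windows), 96.5% for zebrafish Nodal, 71.5% for amphioxus RA (2842 windows) and 2.5% for amphioxus Wnt, so the window test had little power in the last. Each simulation changed 200 windows at once, which makes the adjusted threshold easier to pass. With only a few changed windows the power is lower, so these shares do not give the power in the real lists.

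The other choices, the alternatives not named as later ones, and the rule for named regions were fixed before the data were examined. Named for each treatment are the 3 windows with the smallest p in each direction, the highest-ranked absent control peak and the highest-ranked new peak. Distances to transcription start sites, motif content and fixed gene lists had also been planned. They were not analysed here, because no genome or annotation of the builds of these lists was used. Regions are therefore given by coordinates, counted from 1, with no statement on genes, exons or introns.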

Results

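The 10 peak lists held from 24763 to 210860 regions of accessible chromatin. In zebrafish the control list was the longest, with 210860 peaks over 77.2 Mb. The Nodal and Wnt lists had 172766 and 171218 peaks, and the FGF and RA lists 110212 and 114514. In amphioxus the FGF and Nodal lists, with 42209 and 36388 peaks, were longer than the control list of 33921 peaks over 9.96 Mb. The RA and Wnt lists had 31434 and 24763 peaks. Median peak width lay between 309 and 344 bp in zebrafish and between 250 and 273 bp in amphioxus. The amphioxus Wnt list had the lowest median fold enrichment, 5.62, against 7.12 in its control and up to 8.83 in the RA list. There is 1 list per group, so no value below has an error between replicates. The amphioxus control and FGF lists rest on 4 samples each, and the other amphioxus lists on 2. Differences between FGF and the other amphioxus treatments in length, absent peaks or new peaks can therefore also come from sample number.

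The first question was which regions open in control embryos were missing after each pathway was modified. In zebrafish, FGF and RA treatment went with the largest absences. The FGF list lacked 108921 control peaks, 51.7% (block interval 51.3 to 52.0), and the RA list 104868, 49.7% (49.4 to 50.1). The Nodal list lacked 65696, 31.2% (30.8 to 31.5), and the Wnt list 65290, 31.0% (30.7 to 31.3). Lists shifted along the genome would have lacked on average between 91.7% and 94.6%. Absent peaks were mostly weak ones: their median control percentile was 30.2 for FGF and 22.7 for Wnt, against 73.6 and 64.2 for the peaks held. Among the 21086 control peaks of the top decile, 279 were absent from FGF (1.32%), 154 from RA (0.730%), 63 from Nodal (0.299%) and 50 from Wnt (0.237%). Absent peaks were also narrower, with a median width of 284 bp against 378 bp for held peaks in the FGF comparison. With the zebrafish lists shortened to 110212 peaks each, the order of the treatments was the same and the counts lay closer together, at 28603 (26.0%) for FGF, 26518 (24.1%) for RA, 22872 (20.8%) for Nodal and 21477 (19.5%) for Wnt.

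In amphioxus the Wnt list stood apart. It lacked 16380 control peaks, 48.3% (47.5 to 49.1), against 10283 or 30.3% (29.4 to 31.1) for RA, 9419 or 27.8% (27.1 to 28.4) for Nodal and 6457 or 19.0% (18.5 to 19.6) for FGF. The Wnt absences reached the strongest regions: 534 of 3392 top-decile control peaks were absent, 15.7% (14.5 to 16.9). The FGF, Nodal and RA lists lacked 8, 45 and 27 of these peaks. Of the 534 peaks, 502 were present in the FGF, Nodal and RA lists, all 3 of them. Their median fold enrichment in the control list, 13.0, was close to the 13.3 of the 2858 top-decile peaks that the Wnt list held. Their median −log10 p was lower, at 60.5 against 65.9, and they were narrower, at 335 bp against 355 bp. The widest tercile of the top decile was absent less often, at 11.5% against 17.6% and 18.1% in the narrower ones. The control peaks missing from the Wnt list alone numbered 5790, or 17.1% of the control list. The corresponding numbers were 1523 for RA, 922 for Nodal and 299 for FGF. In zebrafish they were 14481 for FGF, 12145 for RA, 2409 for Wnt and 1848 for Nodal. With the amphioxus lists shortened to 24763 peaks, 9919 control peaks were absent from the Wnt list (40.1%), 6946 from Nodal, 6286 from RA and 6097 from FGF, so that Wnt stayed first and RA and Nodal changed places.

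**Figure D1:**
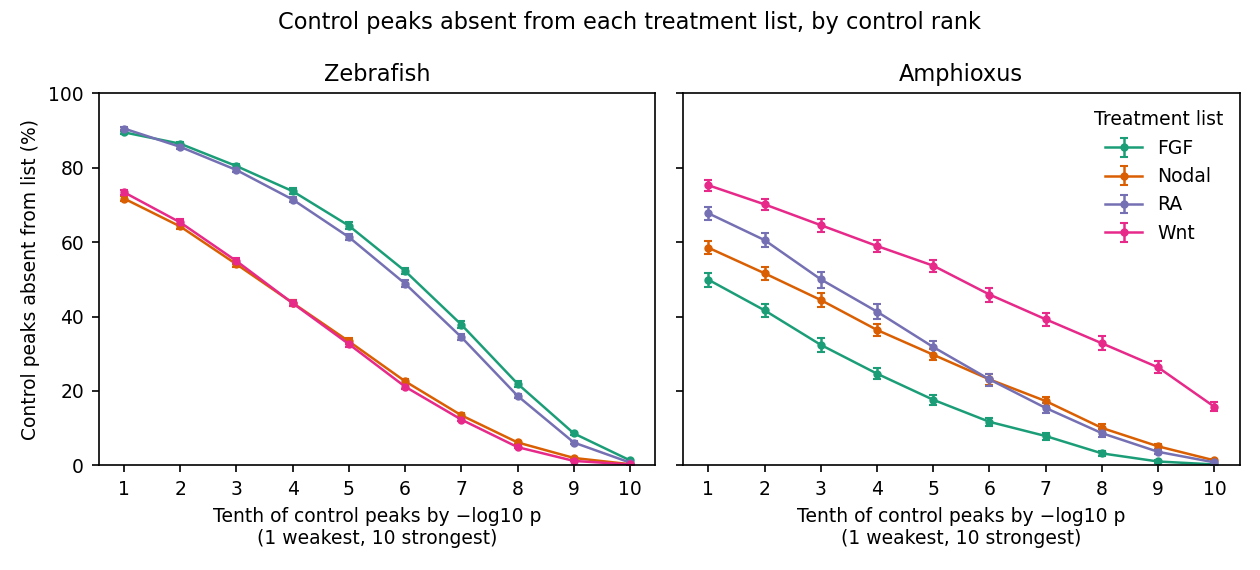
Share of control peaks absent from each treatment list (y axis, %) by decile of control peaks ranked on −log10 p (x axis), in zebrafish and amphioxus. Bars are 95% block-bootstrap intervals. The share falls with rank for each list, to 1.33% or less in the top decile, except for the amphioxus Wnt list at 15.7%.

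The reverse comparison asked which regions were accessible only after treatment. As deposited, new peaks made up a larger share of the amphioxus lists than of the zebrafish lists, and for FGF and RA most of this gap went with list length. In amphioxus, 15188 of the FGF peaks (36.0%, 35.4 to 36.5), 12038 of the Nodal peaks (33.1%), 7250 of the Wnt peaks (29.3%) and 7675 of the RA peaks (24.4%) were new. In zebrafish, 26346 of the Nodal peaks (15.2%, 15.0 to 15.6), 24505 of the Wnt peaks (14.3%), 8058 of the RA peaks (7.04%) and 7424 of the FGF peaks (6.74%) were new. New peaks were weak within their own lists, with median percentiles between 14.2 and 17.2 in zebrafish and between 22.4 and 26.1 in amphioxus. With lists of equal length within a species, the new shares in zebrafish were 25.0% for FGF (27508 peaks), 23.5% for RA (25901), 20.2% for Nodal (22231) and 19.0% for Wnt (20910). In amphioxus they were then 25.7% for FGF (6359), 25.1% for RA (6207), 28.4% for Nodal (7040) and 39.6% for Wnt (9813). Between lists of equal length the new count must lie close to the absent count. These shares therefore largely repeat the absent shares and say little more about regions gained.

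Single loci illustrate both directions in zebrafish (GRCz10). The highest-ranked new peak was at the same place for all 4 treatments, on chromosome 23. Only the shared control list lacked it, so a peak missed in that list cannot be told apart from a gain after treatment. It spans 43500252 to 43500613 in the FGF list, 43500242 to 43500609 in the RA list, 43500233 to 43500610 in the Wnt list and 43500238 to 43500609 in the Nodal list, where it lay at percentile 99.8 with a fold enrichment of 20.9. The highest-ranked control peak absent from the FGF list was on chromosome 4 (59661769 to 59662185), and the Nodal and Wnt lists held it. The one absent from the Nodal list lay on chromosome 14 (19802772 to 19803083), from RA on chromosome 22 (13821414 to 13822019) and from Wnt on chromosome 11 (3860347 to 3860851). Each of these last 3 was present in the other 3 treatment lists. Such peaks were at percentiles 98.2 to 98.9 of the control list.

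Few windows of clustered absent peaks were called in zebrafish. On chromosome 15, from 16800001 to 16900000, the RA list lacked 19 of 19 control peaks (exact binomial test, adjusted p = 0.0224). FGF lacked 17 of them, Wnt 11 and Nodal 10. On chromosome 1, from 56200001 to 56300000, the Wnt list lacked 11 of 11 (exact binomial adjusted p = 0.0326), FGF 11, and Nodal and RA 10 each. No window passed for FGF or Nodal. Of 13000 windows, 829 and 854 had an unadjusted p under 0.05, where a fraction of up to 0.05 would without any clustering. Windows of 200 kb gave 8 calls for Nodal and 5 for RA. The power was limited for FGF and RA, where 26% and 25% of simulated windows with 90% of their peaks absent were called. For a few changed windows, rather than the 200 simulated at once, the power is lower in every list. The leading FGF window, on chromosome 7 from 40900001 to 41000000, lacked 24 of 27 peaks (exact binomial adjusted p = 0.461). The leading Nodal window, on chromosome 17 from 29500001 to 29600000, lacked 12 of 13 (exact binomial adjusted p = 0.101). Among the other windows of smallest p, 27 of 27 control peaks on chromosome 17 from 9700001 to 9800000 were held by the Wnt list (exact binomial adjusted p = 0.218), and on chromosome 8 from 4100001 to 4200000 the RA list lacked 1 of 20 (exact binomial adjusted p = 0.261). The remaining FGF windows of smallest p, on chromosome 17 from 53200001 to 53300000 and on chromosome 9 from 55500001 to 55600000, lacked 4 of 28 and 3 of 23 peaks, fewer than the genome-wide share. The remaining windows of the other lists were on chromosome 20 from 18500001 to 18600000 (Nodal, 10 of 11 absent), chromosome 4 from 17200001 to 17300000 (RA, 22 of 25) and chromosome 17 from 23000001 to 23100000 (Wnt, 15 of 20), none past the threshold. Both called windows were lost when peaks had to overlap by 50% of each, and also when the expected share was taken from peak rank and width, a setting chosen after seeing the data.

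Windows of clustered new peaks passed the threshold in 4 cases for FGF, 8 for RA, 16 for Wnt and 0 for Nodal (828 with an unadjusted p under 0.05), 22 distinct windows in all, each with more new peaks than the genome-wide share. That share was 6.74% for FGF, 7.04% for RA and 14.3% for Wnt. At such low shares a shortfall could hardly be called in windows of this size, so the common direction is not a result. On chromosome 22, from 27700001 to 27800000, all 6 FGF peaks and all 5 Nodal peaks were new, and the control, RA and Wnt lists had none there (FGF exact binomial adjusted p = 0.000494). On chromosome 3, from 60100001 to 60200000, all 6 FGF, 7 Wnt and 3 RA peaks were new and the Nodal list had none. On chromosome 4, from 69000001 to 69100000, all 7 RA, 4 Nodal and 3 Wnt peaks were new and the FGF and control lists had none (RA exact binomial adjusted p = 4.6e-05). On chromosome 22, from 7600001 to 7700000, all 7 RA, 7 Wnt, 4 FGF and 3 Nodal peaks were new and the control list had none (exact binomial adjusted p = 4.6e-05 for RA and 0.0052 for Wnt). In a window without control peaks nearly every treatment peak counts as new, so its share of new peaks follows from that gap in the control list. The leading Wnt window was on chromosome 8 from 35200001 to 35300000, with 10 of 12 peaks new (exact binomial adjusted p = 0.00229). The same window led for Nodal with 7 of 8 (exact binomial adjusted p = 0.0745). Its other windows of smallest p, on chromosome 20 from 53900001 to 54000000 and chromosome 15 from 7900001 to 8000000, had 9 of 13 and 10 of 16 peaks new. On chromosome 3, from 3200001 to 3300000, 6 of 7 FGF peaks were new, and on chromosome 4, from 68900001 to 69000000, all 6 RA peaks. All treatment lists were set against the same control list, so a gap in it can give calls for several treatments at once. Of the windows called for FGF, RA and Wnt, 3, 3 and 6 were also called for another treatment. These counts depend on the settings: windows of 200 kb gave 31 calls for RA, 56 for Wnt and 14 for Nodal, a 50% overlap gave 4 for RA, and expected shares from rank and width gave 4 for RA, 8 for Wnt and 4 for Nodal. Simulated windows of new peaks were called more often than those of absent peaks for FGF and RA, so the counts of the 2 directions cannot be set against each other.

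No amphioxus window passed in either direction for any list, with 100 kb windows giving 1 call for RA absences as the exception among the settings tried. For absent peaks, 66 (FGF) to 243 (Wnt) of 2842 windows had an unadjusted p under 0.05. For new peaks the numbers ran from 37 of 1627 for Wnt to 145 of 3795 for FGF. A fraction of up to 0.05 would be under it without any clustering. The power varied between lists: of simulated windows with 90% of their peaks new, 25.5% were called for FGF, 27.5% for Nodal, 31% for Wnt and 71% for RA. With 90% absent, 82.5% were called for FGF, 52% for Nodal, 46% for RA and 0 for Wnt. The windows named here are therefore those of smallest p and show no difference between pathways that passed a test. On scaffold Sc0000141, from 1 to 50000, the Wnt list lacked 12 of 12 control peaks while FGF lacked 1, Nodal 2 and RA 2 (exact binomial test for Wnt, adjusted p = 0.228). On Sc0000054, from 1550001 to 1600000, the Wnt list held all 17 control peaks and had 26 peaks in total, 6 of them new (exact binomial adjusted p for absence 0.0504). On Sc0000024, from 2650001 to 2700000, RA and Wnt lacked 9 of 9 each, FGF 3 and Nodal 4 (RA exact binomial adjusted p = 0.0614). On xpSc0039674, from 200001 to 250000, RA lacked 7 of 7, Wnt 3, and FGF and Nodal 1 each (RA exact binomial adjusted p = 0.334). On Sc0000172, from 400001 to 450000, the leading window for both FGF and Nodal, Nodal and Wnt lacked 8 of 8, FGF 7 and RA 5 (exact binomial adjusted p = 0.1 for Nodal and 0.172 for FGF). The other windows of smallest p were on Sc0000055 from 1300001 to 1350000 (FGF, 7 of 9 absent), Sc0000019 from 3550001 to 3600000 (FGF, 6 of 8), Sc0000031 from 1450001 to 1500000 (Nodal, 6 of 6), Sc0000068 from 450001 to 500000 (Nodal, 5 of 5), Sc0000016 from 3450001 to 3500000 (RA, 9 of 11) and Sc0000158 from 550001 to 600000 (Wnt, 15 of 17). For new peaks, all 7 FGF peaks on Sc0000266 (1 to 50000) were new (exact binomial adjusted p = 0.861), as were 8 of 9 RA peaks on Sc0000341 (1 to 50000, exact binomial adjusted p = 0.132). The others for new peaks were on Sc0000008 from 5600001 to 5650000 (FGF, 8 of 9 new), the Sc0000054 window above (FGF, 0 of 15), Sc0000139 from 250001 to 300000 (RA, 10 of 13) and Sc0000086 from 50001 to 100000 (RA, 7 of 9). For Nodal they were on Sc0000098 from 100001 to 150000 (9 of 12), Sc0000038 from 1150001 to 1200000 (5 of 5) and Sc0000076 from 550001 to 600000 (5 of 5). For Wnt they were on Sc0000060 from 1200001 to 1250000 (7 of 8), Sc0000050 from 550001 to 600000 (5 of 5) and Sc0000067 from 850001 to 900000 (8 of 11).

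Single amphioxus peaks were named by the same rule as in zebrafish. The highest-ranked control peak absent from the Wnt list, on Sc0000017 (2743174 to 2743486), lay at percentile 99.95 of the control list and was present in the other 3 treatment lists. The highest-ranked peaks absent from Nodal, on xfSc0000000 (320339 to 320690), and from RA, on Sc0001446 (191 to 552), were also present in the other 3 treatment lists, and the one absent from FGF, on Sc0000045 (372565 to 372808), in Nodal and RA. The highest-ranked new RA peak, on Sc0000385 (201993 to 202309), was also in the FGF list, and the new FGF peak, on xfSc0001103 (601 to 1094), in the Nodal list. The new Nodal peak on Sc0001610 (4129 to 4462) and the new Wnt peak on xfSc0034707 (9 to 459) were in all 4 treatment lists. For these too, only the shared control list lacked the peak.

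The title of the series concerns the interconnection of gene regulatory networks, so the next comparison asked whether the regions missing after one treatment were also missing after another. They were, for each of the 6 pairs in both species, beyond what control rank and width predicted. In zebrafish 85649 control peaks were absent from both FGF and RA, against 75091 expected at fixed rank and 54170 from the product of the 2 shares. The odds ratio was 5.06 (4.92 to 5.22). The zebrafish odds ratios ran from 3.91 (3.81 to 4.02) for Nodal and Wnt to 6.71 (6.49 to 6.93) for FGF and Nodal. In amphioxus they ran from 2.55 (2.40 to 2.72) for RA and Wnt, with 7525 peaks observed, 6379 expected and 4966 from the product, to 7.55 (7.0 to 8.11) for FGF and Nodal, with 4782, 2845 and 1793. FGF and Nodal was the pair with the highest odds ratio in both species. The 4 lists of a species were set against the same control list, which could not be split, so part of the excess can come from that list.

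**Figure D2:**
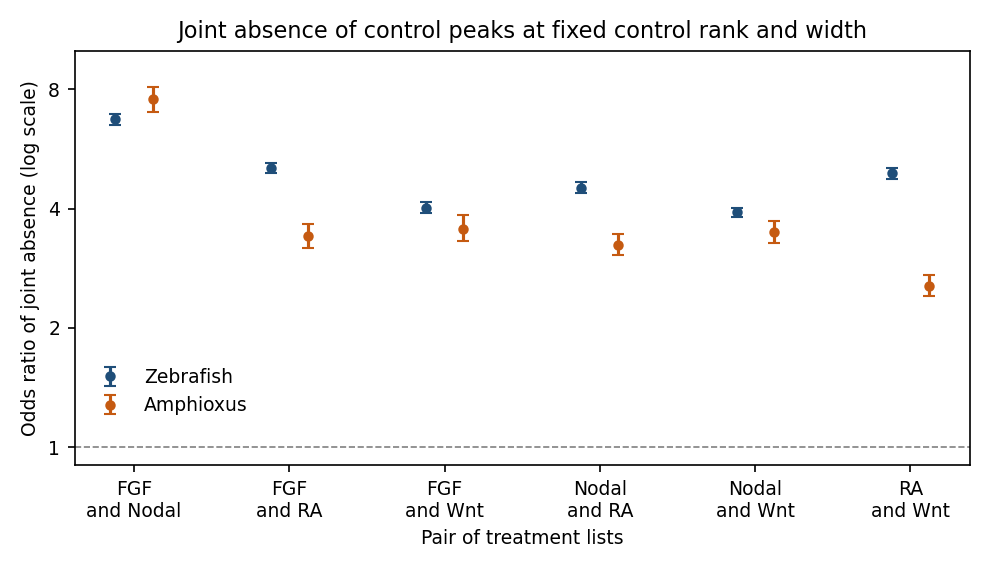
Odds ratio of joint absence of a control peak from 2 treatment lists (y axis, log scale) for the 6 pairs of lists (x axis), at fixed control rank and width. Points are Mantel-Haenszel estimates with 95% block-bootstrap intervals and the dashed line marks independence at 1; the values range from 2.55 to 7.55, and zebrafish lies above amphioxus for 5 of 6 pairs.

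Pairs differed between the species. RA and Wnt absences were tied more closely in zebrafish, with an odds ratio of 4.91 against 2.55 in amphioxus, a ratio of 1.92 (1.79 to 2.06). The ratio was 1.49 (1.38 to 1.60) for FGF and RA, 1.40 (1.30 to 1.48) for Nodal and RA, 1.13 (1.03 to 1.23) for FGF and Wnt and 1.12 (1.05 to 1.19) for Nodal and Wnt. FGF and Nodal went the other way at 0.888 (0.820 to 0.965). Each difference passed the test (bootstrap over genome blocks, not an exact test, adjusted p = 0.0024, or 0.006 for FGF and Wnt). These tests resample the genomes of single lists and not animals. The FGF and Nodal order turned, with zebrafish higher, in 4 of 6 alternative settings and the FGF and Wnt order in 1 of 6. Among control peaks that at least 1 of the other 2 treatment lists held, amphioxus was higher for Nodal and Wnt (2.99 against 2.56), FGF and Wnt (2.96 against 2.72) and FGF and Nodal (6.69 against 5.19). Among peaks held by both other lists, with their ranks there held fixed, amphioxus was also higher for Nodal and RA (2.50 against 1.68), FGF and RA were close (2.23 in zebrafish, 2.20 in amphioxus), and RA and Wnt stayed higher in zebrafish (2.72 against 2.02). Without those ranks, amphioxus was already higher for Nodal and RA among the same peaks (2.81 against 2.67). These species differences were not tested. RA and Wnt, like the other pairs with Wnt, includes the amphioxus Wnt list. Lower enrichment in that list could not be told apart from a response to the treatment, as weighed below. The species difference for this pair can therefore come from the quality of that list. Zebrafish was higher for 4 of 6 pairs among the control peaks of above-median rank and for 6 of 6 pairs when all 10 lists were shortened to 24763 peaks.

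Counted over all 4 treatments, 39095 zebrafish control peaks, 18.5% (18.3 to 18.8), were absent from every treatment list, and 78007 (37.0%) from none. The expected number absent from all 4 at fixed rank was 23216, so the observed was 1.68 times as large (1.67 to 1.70). In amphioxus 3049 control peaks, 8.99% (8.57 to 9.40), were absent from all 4, against 1097 expected, a ratio of 2.78 (2.67 to 2.90). A control peak was missing from 1.63 treatment lists on average in zebrafish (1.62 to 1.65) and from 1.25 in amphioxus (1.23 to 1.27). Both ends of the count were above expectation: 78007 zebrafish peaks were held by all 4 lists against 62150 expected, and 13331 amphioxus peaks against 10571. The peaks missing from 1, 2 or 3 lists were fewer than expected in both species, and so were those missing from 2 or more, 101970 against 107922 in zebrafish and 12056 against 12832 in amphioxus. As a share of the peaks missing from at least 1 list, which were also fewer than expected, those missing from 2 or more came to 76.7% against 72.6% expected in zebrafish and 58.5% against 54.96% in amphioxus. Peaks that only the shared control list holds fall among those absent from all 4, so independent absence is not the value without any treatment effect, and the excess and its species order include such peaks. The species order of the excess over expectation turned with list length. With all 10 lists shortened to 24763 peaks the ratio was 5.01 (4.66 to 5.29) in zebrafish and 2.82 (2.70 to 2.96) in amphioxus.

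New regions were also shared. Merged over treatments, 46183 new regions in zebrafish and 26669 in amphioxus were found. Of these, 31824 (68.9%) and 16304 (61.1%) belonged to 1 treatment, and 1147 (2.48%) and 1009 (3.78%) to all 4. For zebrafish Nodal and Wnt, 9207 new peaks of the Nodal list overlapped new Wnt peaks, against a mean of 242 over 100 shifts. For amphioxus FGF and Nodal the number was 6624 against 115. Over the 12 pairs the observed overlap was between 38.0 and 85.1 times the mean of the shifts and above the highest shift in each. The size of this ratio depends on the setting. It ran from 85.5 to 154.9 with an overlap of 50% of each peak, and from 65.2 to 152.6 among the stronger 50% of new peaks. Shifting ignores that accessible regions lie in preferred places, and a peak missed in the control list counts as new in every treatment list. Shifted peaks that fall in the gaps between sequences also raise the ratios. Amphioxus has more such gaps because its lists lie on more sequences, so the ratios of the 2 species cannot be compared.

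Absent and new peaks were unevenly spread over chromosomes. On zebrafish chromosome 4, 54.8% of control peaks were absent from the RA list against 49.6% elsewhere (Fisher's exact test, adjusted p = 7.21e-15). The shares were 55.4% against 51.5% for FGF, 35.1% against 31.0% for Nodal and 34.5% against 30.9% for Wnt. At fixed rank and width the odds ratios on chromosome 4 were 1.22 (1.05 to 1.41) for RA, 1.16 (1.02 to 1.32) for Nodal, 1.13 (1.00 to 1.28) for Wnt and 1.11 (0.939 to 1.29) for FGF, the last with an interval that holds 1. New peaks were also more frequent there for Wnt (18.2% against 14.2%), RA (9.18% against 6.97%) and Nodal (17.5% against 15.2%), each past the threshold of Fisher's exact test, and 7.62% against 6.71% for FGF (adjusted p = 0.113). Chromosome 4 was chosen after its values were seen. Fisher's tests of absent and of new peaks there treat neighbouring peaks as independent and do not hold rank fixed. The 4 lists are set against the same control list, so their results there are not independent of each other.

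In amphioxus the RA list was the most uneven. The share of control peaks absent from it differed from the rest of the genome on 19 of 76 scaffolds, higher on 12 and lower on 7, with a range from 11.3% on Sc0000076 to 50% on Sc0000066. The Wnt, FGF and Nodal lists had 7, 5 and 3 such scaffolds. These Fisher's tests also treat neighbouring peaks as independent and do not hold rank fixed. On Sc0000004, 267 of 669 control peaks (39.9%) were absent from the RA list against 30.1% elsewhere (Fisher's exact test, adjusted p = 2.3e-05), and 19.0% of its RA peaks were new against 24.5% elsewhere. On Sc0000037 the absent share was 17.6% against 30.4%, and 33.9% of RA peaks were new against 24.4%.

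**Figure D3:**
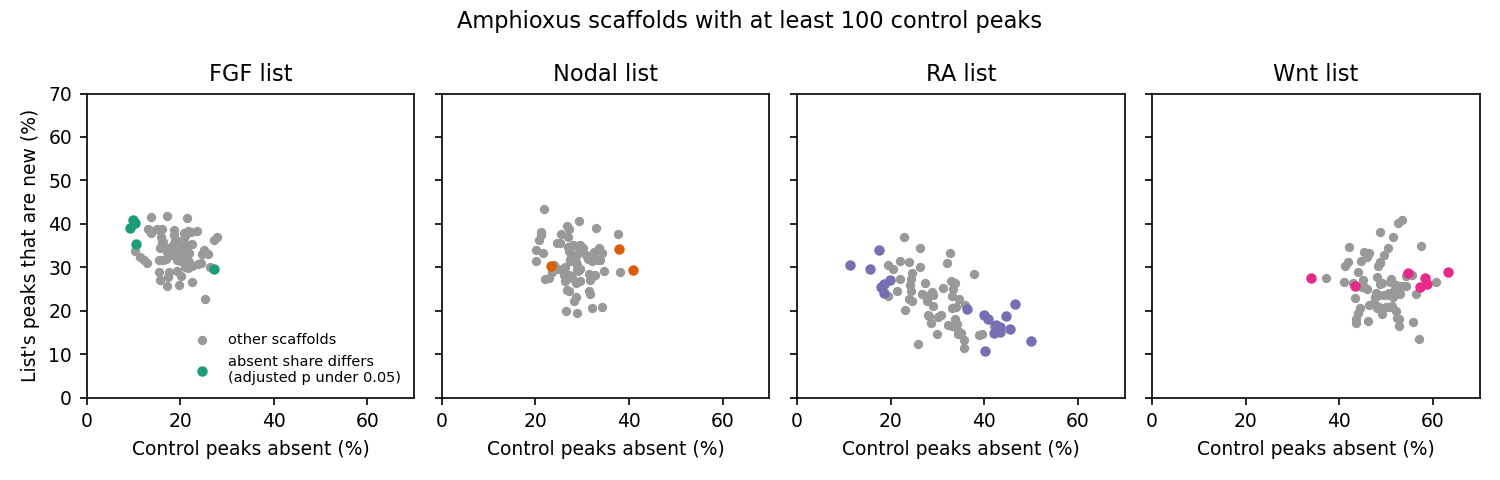
Share of a list's peaks that are new (y axis, %) against the share of control peaks absent from the list (x axis, %) for amphioxus scaffolds with at least 100 control peaks, 1 panel per treatment list. Coloured points are scaffolds whose absent share differs from the rest (adjusted p under 0.05); in the RA panel 19 of 76 scaffolds are coloured and their absent share runs from 11.3% to 50%.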

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

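The tests weighed in this part were written down after the patterns themselves had been seen but before each test was run; shortening all 10 lists to 1 length and ranking by fold enrichment were chosen after seeing the data. List lengths moved in opposite directions in the 2 species for 2 pathways: treatment minus control was -100648 peaks for FGF in zebrafish and 8288 in amphioxus, and -38094 and 2467 for Nodal. These differences between species were not tested, since each is a single list. The amphioxus control and FGF lists rest on 4 samples each and the zebrafish lists on 2 each, so sample number also differs between the species. The odds ratios of joint absence also differed between the species, with zebrafish to amphioxus ratios of 0.888 for FGF and Nodal, 1.49 for FGF and RA, 1.13 for FGF and Wnt, 1.40 for Nodal and RA, 1.12 for Nodal and Wnt and 1.92 for RA and Wnt. The FGF and Nodal order turned in 4 of 6 alternatives, for example to 6.73 in zebrafish against 6.54 in amphioxus with a 50% overlap, and the FGF and Wnt order in 1 of 6, at 4.32 against 4.48 among above-median control peaks. Among peaks held by the other lists further pairs turned, and RA and Wnt stayed higher in zebrafish. That pair includes the amphioxus Wnt list, which had the lowest median fold enrichment of the amphioxus lists. The share of top-decile control peaks absent, amphioxus minus zebrafish, differed by 15.5 percentage points for Wnt (14.2 to 16.8), 1.03 for Nodal (0.633 to 1.43) and -1.09 for FGF (-1.30 to -0.860); for RA the difference of 0.0657 points had an interval that holds 0.

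The first pattern weighed is the joint absence of control peaks from 2 treatment lists. Peaks that only the control list holds would count as absent everywhere, but among control peaks that at least 1 of the other 2 treatment lists held, the odds ratios still ran from 2.24 to 6.69, with all 12 intervals above 1. Control rank is a noisy measure of peak strength; among peaks held by both other lists, adding the rank there took the median log odds ratio to 0.784 of its value among the same peaks, with odds ratios from 1.68 to 4.49 (lowest lower bound 1.56), so this measure of strength is not the whole of it, although a better one could take more. A difference in sample quality or batch between control and treated embryos stays open, since the labels give no batch and no list per sample. Inputs of several pathways to the same regions, the biological explanation the design gives, also stays open as a hypothesis that was not tested.

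The second pattern is the loss of strong control peaks from the amphioxus Wnt list, at 15.7% of the top decile. The FGF, Nodal and RA lists, shortened by rank to the same 24763 peaks, lacked at most 1.98% of the top decile. A cut by rank alone thus did not give such a loss. That outcome was nearly fixed in advance, since the cut takes only the weakest peaks and the top control decile lies high in the RA list. It does not cover a list made short in another way. Lower enrichment in the Wnt libraries cannot be told apart from a response to the treatment. The absent strong peaks had a median percentile of 89.4 in the RA list, and the held ones 94.0. The difference was -4.55 points (-5.68 to -3.51), and its interval crosses the 5 points set beforehand as the limit against this explanation. All these peaks are in the top control decile, so both medians lie near the top of the RA list. That leaves little room for a larger difference, so the test cannot decide. The Wnt list has the lowest median fold enrichment of the 5 amphioxus lists. A candidate explanation is closure of a subset of strong regions after Wnt modification, which values per sample would be needed to test.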

How the results depend on the processing

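Of 214 alternative values for 58 results, 169 kept their direction and side of the threshold, or for counts stayed within 1.5 times. The other 45, all of them counts, moved by more. Of the ratios 0 turned direction, while counts have no direction to turn. Among the 169 are amphioxus window counts that stayed at 0 and many ratios with intervals well away from 1, which had little room to turn. The 45 are therefore a larger share of the counts than of all alternative values. The species comparisons are not among these results. The species order of the odds ratio turned in 4 of 6 alternatives for FGF and Nodal and in 1 for FGF and Wnt. Among peaks held by at least 1 of the other 2 lists it turned also for Nodal and Wnt. Among those held by both it turned for Nodal and RA too, with or without their ranks there. With those ranks only RA and Wnt stayed clearly higher in zebrafish. This pair includes the amphioxus Wnt list, in which lower enrichment could not be told apart from a response. The species order of the excess absent from all 4 lists turned with lists of equal length. In the alternatives all odds ratios of joint absence stayed above 1, from 2.35 with 50% overlap to 19.3 without strata. They ran down to 1.68 among peaks held by both other lists with their ranks there added. The excess absent from all 4 lists also stayed above 1, from 1.66 (zebrafish, 50% overlap) to 13.5 (amphioxus, above-median control peaks). So did that absent from all 3 lists without Wnt, at 1.37 in zebrafish and 2.22 in amphioxus. Ranking by fold enrichment, shortening all 10 lists, leaving out Wnt, the 500 bp margin and rank-based window expectations were chosen after seeing the data. A margin of 500 bp moved no absent count by more than 1.5 times. Counting only the stronger 50% of control peaks for absences and of treatment peaks for new ones, which removes weak peaks by construction, left absent counts for FGF, Nodal, RA and Wnt of 25698, 9376, 22948 and 8380 in zebrafish and 816, 1929, 1750 and 5431 in amphioxus, and new counts of 466, 1968, 566 and 1578 in zebrafish and 2867, 2214, 1122 and 1476 in amphioxus. Lists of equal length gave absent counts of 28603, 22872, 26518 and 21477 in zebrafish and 6286 (RA) and 9919 (Wnt) in amphioxus, and new counts of 27508 (FGF) and 25901 (RA) in zebrafish and 6359 (FGF) and 7040 (Nodal) in amphioxus, so list length sets much of the size of the counts and the order of the new counts, while the order of the absent counts held in zebrafish and changed in amphioxus only between RA and Nodal. Overlap of 50% of each peak raised new counts to 12524 for zebrafish FGF and 12126 for RA. Window calls were the least stable. Absent windows of 200 kb numbered 8 for zebrafish Nodal, 5 for RA and 0 for Wnt, and new windows 14 for Nodal, 31 for RA and 56 for Wnt; in amphioxus, windows of 100 kb gave 1 for RA absences. With 50% overlap, RA and Wnt absent windows fell to 0 each and RA new windows to 4. With expected shares from rank and width, absent windows came to 1 for FGF, 1 for Nodal, 0 for RA and 0 for Wnt, and new windows to 4 for Nodal, 4 for RA and 8 for Wnt; the cause was not tested. No paired analysis was possible because each deposited list stands for a whole group, and for the same reason no replicate could be left out and no other split of the samples be tried. The alternatives listed beforehand for start-site distance, motifs and gene lists were not run, since no matching annotation was used. Unknown read depth limits all counts of absent and new peaks.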

Other observations

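The correlation test in this part was chosen after the uneven scaffolds had been seen; the test at fixed rank was written before it was run. On zebrafish chromosome 9 new peaks were more frequent than elsewhere for all 4 treatments, at 9.21% against 6.62% for FGF, 9.47% against 6.93% for RA, 17.5% against 15.2% for Nodal and 16.3% against 14.2% for Wnt (Fisher's exact test, adjusted p from 1.54e-09 for FGF to 1.36e-05 for Wnt). This chromosome and the scaffolds that follow were chosen after their values were seen. Their tests treat neighbouring peaks as independent and do not hold rank fixed. New peaks in all 4 lists are counted against the same control list, so the results of the 4 lists are not independent of each other. In amphioxus, new peaks were less frequent on Sc0000003 and Sc0000011 than elsewhere in all 4 treatment lists, at 14.8% and 15.5% in the RA list, 20.7% and 21.3% in Wnt, 26.9% and 23.3% in Nodal and 30.1% and 29.0% in FGF, against 24.6%, 29.4%, 33.2% and 36.1% elsewhere.

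Over 76 amphioxus scaffolds, the share of control peaks absent from the RA list fell as the share of new RA peaks rose. Spearman's rho was -0.681 (-0.784 to -0.548) and Pearson's r -0.645, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and r was -0.618 without the 2 scaffolds farthest from the median. Scaffolds are not independent replicates. For FGF, Nodal and Wnt, rho was -0.260, -0.134 and -0.0193 (permutation p = 0.024, 0.25 and 0.87, and 0.048, 0.33 and 0.87 adjusted over the 4 lists, against 4e-05 for RA), and the differences between lists were not tested. Weaker control peaks on some scaffolds are argued against by the odds ratios at fixed rank and width. They stayed away from 1 on the 19 called scaffolds, from 0.236 on Sc0000076 to 3.21 on Sc0000066. All 19 intervals leave out 1, but on short scaffolds they rest on few blocks and can understate the error. On Sc0000066, with 130 peaks, the interval was 3.03 to 3.44. The 19 scaffolds were also called on the same absences, so their number adds little support. A shift of signal over whole scaffolds is consistent with the negative correlation: a scaffold with less signal would both lose control peaks and gain few new ones. Such a shift could come from the parents of the RA embryos, from copy number or from library preparation, none of which was tested; the hypothesis would place part of the RA difference above the level of single regulatory regions.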
